A study of Homo sapiens with 12 samples.

How the data were processed

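Gene-level tables for 12 THP-1 RNA-seq libraries were used, 1 table of estimated counts and 1 of FPKM, with the same 62914 entries each. The estimated counts and the FPKM values were, per the submitters' processing notes, made with RSEM against GRCh38 before the tables were deposited. No RSEM version, annotation release, read strand or vehicle for the untreated group is given in the sources used here. The notes also name DESeq2 1.26.0 for the authors' own tests, whose results are not used here. Libraries were made from oligo(dT)-selected RNA and run on a BGI DNBSEQ instrument, per the labels. The estimated counts were not whole numbers in 42.307% of cells above 0 and were rounded before testing. Every per-sample column was used (0 left out).

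Entries comprised 62588 Ensembl gene IDs, 62517 of them with a symbol, and 326 unannotated transcripts. Positions come from GENCODE 29 on GRCh38 for 58167 IDs, and 34815 IDs had at least 1 count in any library. GCLC, CENPA and MERTK of the lists were not matched by symbol and are not analysed here. A gene that the naming rule or the lists would bring in is not reported here. Since strand is not known, reads from overlapping genes on opposite strands may be exchanged, which touches antisense genes, TAP1 with PSMB9, and MT-ND6. Pseudogenes and near-identical copies (HSPA1A with HSPA1B, the MT1 genes, FTH1) may share reads too.

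The following choices were made before the data were examined: groups, comparisons, tools, thresholds, alternatives, the 17-gene panel and the gene lists. Counts were filtered with filterByExpr (minimum count 10), scaled by TMM and fitted with edgeR 4.0.16 quasi-likelihood in R 4.3.3, as 1 model of 12 libraries and 4 groups. The adjusted p-values of single genes are edgeR quasi-likelihood F-test p-values after Benjamini-Hochberg correction over the 16628 tested genes, called below 0.05. The SE of a log2 change is its size over the square root of the F statistic. Scaling factors ran from 0.9048 to 1.061. Each scaling centres on the bulk of genes, so all changes are relative to it and a change in total RNA per cell cannot be seen. The spread estimate had 8 residual and 8.99 prior degrees of freedom. Replicates varied more in the chlorquinaldol groups, so 1 shared spread may be too wide for cGAMP and too narrow for the drug. Principal components and library correlations used log2 CPM with a prior count of 2, the former on 500 genes. With 3 against 3 the smallest exact p of a single comparison is 0.1, so the tests rely on the spread pooled over genes.

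Gene lists with at least 3 tested members were tested with camera of limma 3.58.1 at the preset correlation of 0.01 between genes, and adjusted over lists within a comparison. Camera asks whether a list moves relative to other genes. The preset correlation gives small p-values when members move together for other reasons, and the estimated correlation, taken from the same 12 libraries, is the stricter answer. Fry was run as well: its directional p asks whether a list moves 1 way on balance and its Mixed p whether members move in either direction, and neither compares with other genes. List p-values in the text, and the ranges over alternatives beside them, are camera p-values. Counts adjusted over the list alone use Benjamini-Hochberg within the list.

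The 30 lists, written from general knowledge of gene function, were interferon-stimulated genes, type I and III interferons, nucleic acid sensing, NF-kB and inflammatory cytokines, metallothioneins and zinc, heat shock, NRF2 targets, ATF4 and amino acid response, endoplasmic reticulum chaperones, hypoxia, iron homeostasis, p53 targets, G2/M, S phase, cholesterol synthesis, ribosome biogenesis, mitochondrially encoded genes, proteasome, MHC class I, MHC class II, immediate early genes, inflammasome, autophagy and lysosome, monocyte identity, macrophage differentiation, and markers of T and NK cells, B cells, epithelium, fibroblasts, and erythroid and megakaryocyte cells.

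Genes were named by a fixed rule: the 6 largest increases and decreases per comparison with a symbol, adjusted p below 0.05, at least 5 CPM in the higher group and libraries that do not overlap; the members with the smallest p of up to 8 lists with the smallest camera p; and the panel IFNB1, IFIT1, ISG15, MX1, CXCL10, TNF, CXCL8, HMOX1, MT2A, HSPA1A, DDIT3, TFRC, VEGFA, CDKN1A, MKI67, STING1 and CGAS. Further list members and MT-RNR1 and MT-RNR2 were picked as examples after their values were seen. With 3 counts or fewer in a group, a ratio of scaled counts is given with a 95% counting interval, and with 0 counts a lower bound.

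Alternatives were DESeq2 1.42.0, RLE and upper-quartile factors, no filter, at least 5 CPM in 3 libraries, only the groups compared, a replicate block, limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) of the deposited FPKM, all FPKM genes, adjusted p below 0.01, at least 2-fold, and each library left out in turn. Overlaps were compared with 50 simulations of groups without change that share controls, 10 of them refitted for calls. In a self-test on simulated counts with the untreated means and the fitted spread, 200 genes were changed by known amounts. They were drawn from genes with a mean of at least 20 counts in the untreated libraries, so recovery at lower counts is not known. Of 2-fold changes (log2 1), edgeR recovered 94%, 92.5% and 88.1% for cGAMP, 20 μM and 50 μM, with 4%, 6.3% and 2.4% of calls false. The simulation changed few genes, in both directions, with 1 spread for all groups. Far more genes were called in the data (23.3%, 55.1% and 66.9% of those tested), so these rates may not hold there.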

Results

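THP-1, an established human monocytic leukemia cell line, was profiled by RNA sequencing in 12 libraries forming 4 groups of 3: untreated cells, cells given 1 μg/mL 3'-3'-cGAMP, cells given 20 μM chlorquinaldol and cells given 50 μM chlorquinaldol, each treatment for 8 h. The cyclic dinucleotide 3'-3'-cGAMP binds STING, the adaptor of cytosolic DNA sensing. Chlorquinaldol is a chlorinated hydroxyquinoline used as a topical antiseptic, and hydroxyquinolines bind metal ions. Libraries held 18910085 to 19023005 gene-assigned counts in untreated cells, 18914542 to 18979948 with cGAMP, 17620929 to 18926562 at 20 μM and 19011578 to 19222607 at 50 μM. After filtering, 16628 genes were tested in 1 edgeR model. Levels are CPM, scaled by library size, mean ± SD with n = 3, and log2 changes carry ± SE. Where the replicates came from is not stated, so every p-value measures only the spread between these samples. No time or vehicle is stated for the untreated cells. Differences from them may therefore include effects of solvent or harvest time, which cannot be told apart from those of the treatments.

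The 500 most variable genes placed the chlorquinaldol groups apart from the others on the first principal component (67.1% of variance). Its scores ran from −31.86 to −29.33 in untreated cells, −36.59 to −34.57 with cGAMP, 14.71 to 25.47 at 20 μM and 41.99 to 49.28 at 50 μM. The second component (17.7%) held cGAMP at 23.68 to 25.09 and untreated cells at −24.15 to −21.64. Library correlations were 0.9856 to 0.9912 within groups and 0.9037 to 0.9764 between them. Gene calls, at an adjusted p below 0.05, numbered 1921 higher and 1954 lower for cGAMP against untreated cells, 4501 and 4654 for 20 μM, and 5352 and 5771 for 50 μM. At least 2-fold changes numbered 617 and 104, 1459 and 1028, and 2393 and 2134, in the same order. Calls made up 23.3%, 55.1% and 66.9% of the tested genes, and 50.4%, 50.8% and 51.9% of the calls were lower. A list with calls in both directions near these shares is not set apart from other genes.

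cGAMP was compared with untreated cells to show which transcripts a STING agonist changed in these cells. All 56 interferon-stimulated genes tested rose, also when adjusted over the list alone, with a median log2 change of 4.27. IFIT1, which encodes an interferon-induced protein that binds viral RNA (ENSG00000185745, chromosome 10, 89392546 to 89406486), went from 2.36 ± 0.738 to 578 ± 22.2 CPM, 244-fold (log2 7.93 ± 0.25, adjusted p = 1.55e-13). The chemokine gene CXCL10 rose 322-fold (log2 8.33 ± 0.36), IFIT2 240-fold, CXCL11 178-fold, the antiviral GTPase gene MX1 75-fold and the ubiquitin-like modifier gene ISG15 63.1-fold. The list differed from other genes with an estimated correlation too (adjusted p = 0.000205). Interferon beta, IFNB1 (chromosome 9, 21077105 to 21077963), had 708 counts over the cGAMP libraries and 3 over the untreated ones, a ratio of 246 with a 95% counting interval of 83.7 to 1195. The ubiquitin ligase gene TRIM31 had 457 against 1 (ratio 476, interval 85 to 18837). Over all 21 interferon genes of the fixed list, of which IFNB1 and IFNL1 were tested, the counts were 781 against 3.

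cGAMP also raised antigen-processing genes and DNA sensors. In the MHC class I list 16 of 18 genes rose and none fell, the same adjusted over the list alone (median log2 0.65; adjusted p = 0.0241 with an estimated correlation). TAP1, a peptide transporter, rose 5.95-fold from 64.4 ± 2.01 to 383 ± 51 CPM, and the immunoproteasome gene PSMB9 3.67-fold. These neighbours overlap in position, so unstranded reads may be shared. In the nucleic acid sensing list 11 of 30 rose and 3 fell (13 and 5 adjusted over the list alone; adjusted p = 0.0238 with an estimated correlation). IFI16, a nuclear and cytosolic DNA sensor, rose 16.7-fold to 303 ± 12.4 CPM, AIM2 by log2 5.67, and CGAS by 0.46. STING1 itself was not called (log2 −0.21 ± 0.08, adjusted p = 0.0601). Its call as lower was gained with upper-quartile scaling (0.0261) and with at least 5 CPM in 3 libraries (0.0489). It was also gained in limma on FPKM (0.0259 and 0.0278 with pseudocounts 1 and 0.1). The alternatives ran from 0.0259 to 0.293. Inflammatory genes divided: CCL8 (log2 6.28) and CCL7 (3.58) rose while CXCL3 (−2.30), IL1B (−1.80) and CXCL8 (−1.24) fell. In the NF-kB and inflammatory list 8 of 38 rose and 5 fell (10 and 9 adjusted over the list alone), and camera did not call it (adjusted p = 0.276).

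Further changes with cGAMP were smaller or confined to few genes. Macrophage differentiation genes rose in 7 of 17 cases (8 adjusted over the list alone), among them the scavenger receptor gene MSR1 3.84-fold. That list had an adjusted p = 0.00636 by camera and 0.872 with an estimated correlation. Inflammasome genes rose in 6 of 14 (8 rose and 1 fell adjusted over the list alone), with CASP1 2.58-fold higher (0.0295, and 0.394 with an estimated correlation). Proteasome genes rose in 7 of 31 and fell in 1, the same adjusted over the list alone, led by PSMA4 at log2 1.26. The proteasome call (0.0387) ended with an estimated correlation (0.973), upper-quartile scaling (0.0626), without control replicate 1 (0.0871) and without cGAMP replicate 2 (0.065), with alternatives from 0.0143 to 0.973. PAX5, a B-lineage transcription factor gene, rose 54.6-fold from 1 ± 0.143 to 55.2 ± 10.3 CPM. In the B-cell list of 3, PAX5 rose and CD79B fell (log2 −0.44, adjusted p = 0.0465, lost without any 1 library, 0.0745 to 0.136; 1 and 2 adjusted over the list alone), so the median of −0.39 opposes the mean of 1.65 and the upward camera result (0.00297, and 0.0573 with an estimated correlation). The metallothionein gene MT2A rose 3.15-fold, CDKN1A by log2 0.92 and DDIT3 by 0.50 (adjusted p = 0.014).

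The largest decreases with cGAMP among genes with at least 5 CPM in untreated cells and libraries that do not overlap included activity-induced and inflammatory genes: EGR3 fell 7.75-fold, IL1B 3.47-fold, EGR1 by log2 −1.35, FOSB by −1.29, CXCL8 2.37-fold and PRAM1 by −1.18. Immediate early genes rose in 2 and fell in 4 of 22 (3 and 6 adjusted over the list alone). TNF (log2 −0.61, adjusted p = 0.0695), HMOX1 (0.74, 0.062), HSPA1A (−0.13, 0.593), TFRC (−0.20, 0.12), VEGFA (0.04, 0.827) and MKI67 (−0.22, 0.221) were not called. No other fixed list differed from other genes by camera (adjusted p from 0.124 to 0.972), including cholesterol synthesis and G2/M genes, though S phase was gained without control replicate 3 (0.0406). The 3 IFNB1 counts of untreated cells were all in control replicate 2 and the 1 of TRIM31 in control replicate 1, so the untreated counts are 0 without these libraries. Other folds moved when a library was left out: log2 9.69 for CXCL10 without control replicate 1, and −1.97 for EGR3 without control replicate 3. DDIT3 was lost without control replicate 1 (0.083), control replicate 2 (0.0604) or cGAMP replicate 3 (0.0608; alternatives 2.51e-07 to 0.132), TNF was gained without control replicate 1 (0.0456; alternatives 7.41e-08 to 0.271), TNF (0.000316) and HMOX1 (1.64e-05; alternatives 1.82e-11 to 0.334) were gained with only the groups compared, and lower calls numbered 858 without cGAMP replicate 2.

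**Figure D1:**
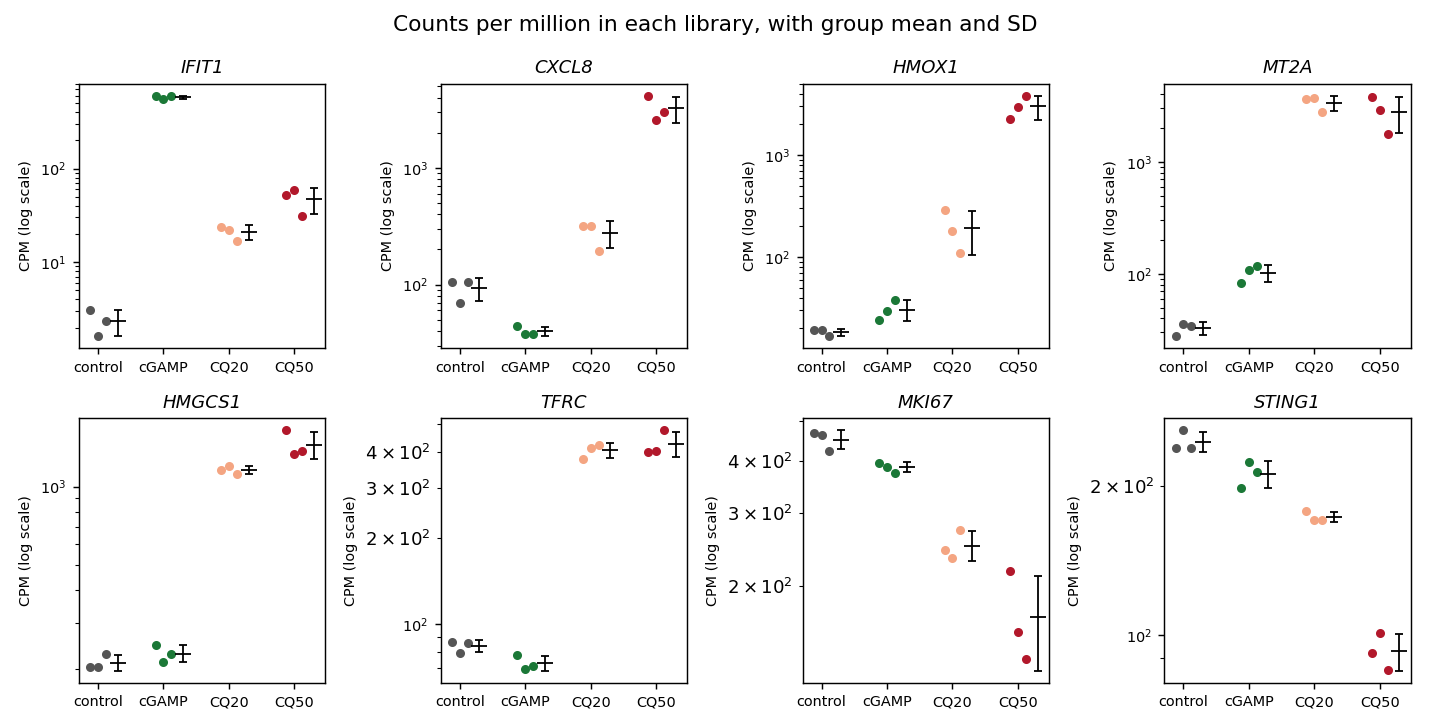
CPM per library on a log axis for IFIT1, CXCL8, HMOX1, MT2A, HMGCS1, TFRC, MKI67 and STING1 in the 4 groups, with group mean and SD (n = 3). IFIT1 peaks with cGAMP at 578 CPM, while MT2A rises from 32.6 to 3370 CPM at 20 μM and STING1 falls to 92.7 CPM at 50 μM.

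Chlorquinaldol at both doses was compared with untreated cells. Under the naming rule the largest increases at 20 μM, and some of the largest at 50 μM, were in metallothionein genes, which encode small zinc- and copper-binding proteins. MT2A (chromosome 16, 56608199 to 56609497) went from 32.6 ± 4.25 to 3370 ± 527 CPM at 20 μM (103-fold, log2 6.69 ± 0.26, adjusted p = 9.64e-12) and 2799 ± 996 at 50 μM (85.8-fold). MT1M rose 2830-fold and 2211-fold, and MT1B, with 0 untreated counts, at least 774-fold and 528-fold. SLC30A1, a zinc exporter gene, rose 7.59-fold and 8.02-fold. In the metallothionein and zinc list 11 of 12 genes rose at both doses, the same adjusted over the list alone. The zinc importer gene SLC39A10 was the member that fell (log2 −2.33 and −2.50). List medians were 6.49 and 6.02, or 5.85 and 5.93 with low-count members at their bound. Its adjusted p was 0.0461 at 20 μM and 0.159 at 50 μM with an estimated correlation. Camera at the preset correlation gave 6.98e-13 at 50 μM. MT1 paralogs are similar in sequence, so counts may pass between copies.

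Sterol and hypoxia genes rose with the drug, while iron genes moved both ways. HMGCS1, which encodes the sterol-pathway synthase before HMG-CoA reductase (chromosome 5, 43289395 to 43313512), went from 212 ± 15.2 to 1158 ± 38.3 CPM at 20 μM (5.47-fold) and 1447 ± 169 at 50 μM (6.83-fold). Cholesterol synthesis genes rose in 22 of 24 and fell in 0 at 20 μM (22 and 1 adjusted over the list alone), then rose in 23 and fell in 1, PMVK, at 50 μM, the same adjusted over the list alone (medians 1.36 and 1.72; adjusted p = 0.0461 and 0.11 with an estimated correlation). At the preset correlation camera gave 1.13e-20 for cholesterol synthesis at 50 μM. Hypoxia genes rose in 33 of 36 and fell in 1 at 20 μM and rose in 34 with none lower at 50 μM, the same adjusted over the list alone (medians 1.11 and 1.54). Camera gave them 3.74e-24 and 2.07e-22 at the preset correlation, and 0.188 and 0.17 with an estimated correlation. ANGPTL4, a lipase inhibitor gene, rose by log2 4.88 and 7.2, and VEGFA 2.18-fold and 4.26-fold. FLT1, a VEGF receptor gene, rose 212-fold at 50 μM to 142 ± 11.6 CPM, and ERO1A 4.85-fold. The transferrin receptor gene TFRC rose 4.83-fold and 5.08-fold from 83.8 ± 4.18 CPM, while the ferrireductase gene STEAP3 fell (log2 −1.63 and −2.68). The iron list rose in 6 and fell in 4 of 14 at 20 μM, and 6 and 5 at 50 μM, the same adjusted over the list alone (camera 0.0293 and 0.0791; 0.195 at 20 μM with an estimated correlation).

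Oxidative-stress genes rose steeply with dose. HMOX1, the heme oxygenase gene (chromosome 22, 35380361 to 35394214), went from 18.3 ± 1.37 to 193 ± 88.9 CPM at 20 μM (10.5-fold) and 3003 ± 788 at 50 μM (164-fold, log2 7.35 ± 0.33, adjusted p = 5.17e-12). FTH1, ferritin heavy chain, rose 9.36-fold and 23-fold, to 23298 ± 1857 CPM. The NADPH-producing enzyme gene ME1 rose by log2 2.03 and 3.58, while AKR1C3 fell (−1.54 at 50 μM). NRF2 targets rose in 22 and fell in 4 of 30 at 20 μM (22 and 5 adjusted over the list alone), and 26 and 3 at 50 μM, the same adjusted over the list alone (medians 0.72 and 1.96). Camera gave an adjusted p = 2.43e-07 and 1.67e-17 at the preset correlation, and 0.258 and 0.125 with an estimated correlation. ATF4 targets rose in 14 and fell in 12 of 37 at 20 μM (15 and 12 adjusted over the list alone; camera 0.245), then 25 and 3 at 50 μM, the same adjusted over the list alone (2.9e-05, and 0.251 with an estimated correlation), with ATF3 at log2 4.14 and GDF15 at 4.04. DDIT3 rose by log2 1.06 and 1.86. CDKN1A, a cell-cycle inhibitor gene, rose 4.61-fold and 8.47-fold, but TIGAR fell (−1.50 and −1.02). p53 targets rose in 12 and fell in 3 of 24, then 13 and 7, the same adjusted over the list alone (camera 0.0329 and 0.0262; 0.424 and 0.321 with an estimated correlation).

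Heat shock and proteasome genes fell more often than they rose, while autophagy and lysosome genes rose more often than they fell. HSPA1A, whose transcript is nearly identical to that of HSPA1B, fell (log2 −0.66 and −0.90), as did AHSA1 at 20 μM (−1.02). Heat shock genes rose in 3 and fell in 17 of 28 at 20 μM (camera 0.0115, and 0.447 with an estimated correlation) and 5 and 14 at 50 μM (camera 0.251), the same adjusted over the list alone. Endoplasmic reticulum stress genes rose in 7 and fell in 6 of 22, then 9 and 6, and camera called neither (0.934 and 0.906). Proteasome genes fell in 18 and rose in 2 of 31 at 20 μM, PSMA7 by log2 −0.84 (19 and 2 adjusted over the list alone; camera 0.00906, and 0.534 with an estimated correlation), with 14 lower and 6 higher at 50 μM, the same adjusted over the list alone (camera 0.251). Autophagy and lysosome genes rose in 19 and fell in 5 of 31 at 20 μM, the same adjusted over the list alone, and 19 and 4 at 50 μM (20 and 4 adjusted over the list alone). The cargo receptor gene SQSTM1 rose by log2 0.73 and 2.66 and the cathepsin gene CTSL by 0.94 and 3.30; this list had 0.0152 and 3.12e-05 by camera and 0.447 and 0.251 with an estimated correlation.

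Inflammatory genes rose in part at 20 μM and broadly at 50 μM. CXCL8, the neutrophil chemokine gene (chromosome 4, 73740506 to 73743716), went from 94.1 ± 21.1 to 276 ± 71.3 CPM (2.94-fold) and 3260 ± 813 CPM (34.6-fold, log2 5.11 ± 0.23, adjusted p = 5.28e-12). IL1A rose by log2 7.02 and IL1B by 4.60 at 50 μM, TRAF1 20.2-fold, and TNF 3.33-fold then 2.31-fold. In the NF-kB and inflammatory list 23 of 38 rose and 1 fell at 20 μM (24 and 1 adjusted over the list alone), and 36 rose with none lower at 50 μM, the same adjusted over the list alone. Medians were 0.65 and 2.88. Camera gave an adjusted p = 6.49e-05 and 1.11e-19 at the preset correlation, and 0.447 and 0.178 with an estimated correlation. Immediate early genes rose in 15 of 22 at both doses and fell in 2 and 1, the same adjusted over the list alone (0.000145 and 3.18e-05; 0.422 and 0.321 with an estimated correlation), NR4A3 by log2 2.73 and 5.51. Inflammasome genes rose in 8 and fell in 3 of 14 (9 and 3 adjusted over the list alone), then 10 and 3, the same adjusted over the list alone (0.00941 and 0.00443; 0.212 and 0.178 with an estimated correlation). NLRP1 rose (log2 2.24 and 2.03) and NAIP fell (−0.74 and −2.04).

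Interferon-stimulated genes rose with chlorquinaldol to lower levels than with cGAMP. IFIT1 reached 20.9 ± 3.77 CPM at 20 μM (8.8-fold) and 47.2 ± 14.6 at 50 μM (19.9-fold). ISG15 rose 2.33-fold and 5.51-fold, MX1 2.72-fold and 6.87-fold, IFIT3 16.4-fold at 50 μM and CXCL10 3.3-fold and 32.2-fold. The list rose in 46 and fell in 1 of 56 at 20 μM (47 and 2 adjusted over the list alone) and 51 and 1 at 50 μM, the same adjusted over the list alone, with IFITM2 the gene that fell. Medians were 1.16 and 2.06. Camera gave an adjusted p = 1.8e-20 and 5.25e-27 at the preset correlation, and 0.212 and 0.178 with an estimated correlation. IFNB1 had 4 and 6 counts against 3 (ratios 1.37, interval 0.232 to 9.37, and 2.19, interval 0.467 to 13.5) and was not called; the 21 interferon genes together had 5 and 7 against 3. Without control replicate 2 the untreated group has 0 IFNB1 counts, and the adjusted p = 0.025 found then at 50 μM (alternatives to 0.678) rests on 6 counts against none. CXCL10 at 20 μM (adjusted p = 0.0369) was lost without control replicate 2 (0.134), control replicate 3 (0.124), CQ20 replicate 1 (0.114) or CQ20 replicate 2 (0.0582; alternatives 1.2e-06 to 0.134), and without control replicate 1 it was at log2 3.08 and, at 50 μM, 6.36.

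Sensor and antigen-presentation genes moved both ways. STING1 (ENSG00000184584, chromosome 5, 139475534 to 139482935) fell from 246 ± 11.8 to 173 ± 4.03 CPM at 20 μM (1.42-fold) and 92.7 ± 7.98 at 50 μM (2.65-fold, log2 −1.41 ± 0.08, adjusted p = 1.09e-10). CGAS was not called at 20 μM (log2 0.15, adjusted p = 0.12; 0.0345 without CQ20 replicate 3; alternatives to 0.311) and rose 1.27-fold at 50 μM. The sensing list rose in 12 and fell in 7 of 30 (12 and 8 adjusted over the list alone; camera 0.503), then 16 and 7, the same adjusted over the list alone (0.0853), with IFI16 (log2 2.55) and TLR7 (2.45) higher at 50 μM and IRF5 lower (−1.30). MHC class I genes fell in 15 of 18 at 20 μM with ERAP2 higher (log2 1.04), the same adjusted over the list alone, and the transactivator gene NLRC5 fell by log2 −1.24 (0.000163, and 0.212 with an estimated correlation). At 50 μM 10 fell and 4 rose, the same adjusted over the list alone (camera 0.078). MHC class II genes rose in 4 and fell in 3 of 10 (4 and 4 adjusted over the list alone), then 4 and 4 (4 and 5 adjusted over the list alone), and camera called neither (0.721 and 0.906).

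**Figure D2:**
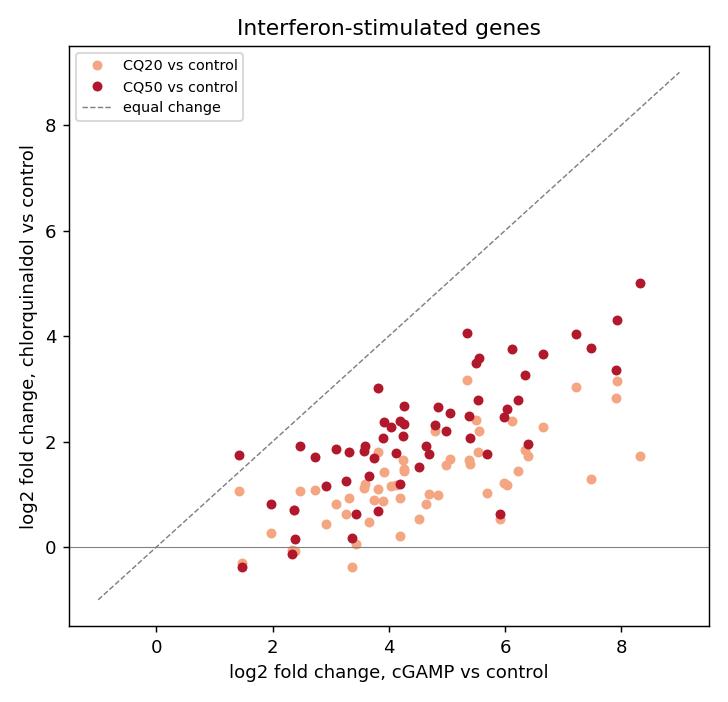
Log2 change against untreated cells of 56 interferon-stimulated genes, cGAMP on the x axis and each chlorquinaldol dose on the y axis, with the line of equality. Most points lie above 0 and below the line; medians are 4.27 for cGAMP, 1.16 at 20 μM and 2.06 at 50 μM.

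G2/M genes fell at both doses, and S-phase genes fell at 50 μM. CDC20, an activator of the anaphase-promoting complex, went from 542 ± 16.7 to 117 ± 16 CPM at 20 μM (4.65-fold lower) and was 6.09-fold lower at 50 μM. The mitotic kinase gene PLK1 was 7.06-fold lower at 50 μM, and MKI67 fell from 451 ± 23.5 to 250 ± 20.9 and 168 ± 43.3 CPM. G2/M genes fell in 26 of 29 with CDK1 higher at 20 μM (27 and 1 adjusted over the list alone), and in all 29 at 50 μM, the same adjusted over the list alone (medians −0.91 and −1.66). Camera gave an adjusted p = 1.17e-16 and 1.01e-22 at the preset correlation, and 0.188 and 0.125 with an estimated correlation. S-phase genes rose in 13 and fell in 4 of 33 at 20 μM (12 and 4 adjusted over the list alone; camera 0.0779), CCNE2 by log2 1.23 and TK1 by 1.15. At 50 μM 2 rose and 22 fell, the same adjusted over the list alone, MCM3 by −1.16 and CLSPN by −1.12 (0.000829, and 0.409 with an estimated correlation). The S-phase call at 20 μM was gained without control replicate 2 (0.0377) or CQ20 replicate 1 (0.0185; alternatives to 0.678). Ribosome biogenesis genes fell in 23 of 25 at 20 μM, the same adjusted over the list alone, and in 19 at 50 μM (20 adjusted over the list alone). Medians were −1.05 and −0.87. Camera gave 5.48e-11 and 0.000112 at the preset correlation, and 0.212 and 0.407 with an estimated correlation. The RNA polymerase I subunit gene POLR1A fell by log2 −1.75 and −1.76, and MYC by −1.11 and −0.65.

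Mitochondrially encoded mRNAs fell while the mitochondrial ribosomal RNAs rose. MT-CO1, a cytochrome oxidase subunit gene, went from 12921 ± 914 to 1383 ± 684 CPM at 50 μM (log2 −3.22 ± 0.29, adjusted p = 2.57e-08), after −1.75 at 20 μM. MT-ATP8 fell 9.3-fold and MT-ND4L 7.05-fold at 50 μM. Of the 13 protein-coding genes 11 fell at 20 μM and 13 at 50 μM, the same adjusted over the list alone (medians −1.40 and −2.86; 0.000776 and 3.51e-07 by camera; 0.447 and 0.281 with an estimated correlation). MT-RNR1, outside the list, rose 3.19-fold and 2.18-fold, and MT-RNR2 by log2 0.36 and 0.66. The 20 μM libraries differed: the rRNA share was 1.951% and 1.799% of counts in CQ20 replicates 1 and 2 but 1.234% in CQ20 replicate 3, inside the untreated range of 1.155% to 1.242%. MT-ND3 (log2 −0.80, adjusted p = 0.131) and MT-CYB (−0.65, 0.0922) were not called at 20 μM. With cGAMP the 13 mRNAs were lower too, by log2 −0.19 to −0.67, but only MT-ATP8 was called (adjusted p = 0.0264). Their share of counts was 3.355% to 3.615% with cGAMP and 4.207% to 4.926% in untreated cells. Set against cGAMP, MT-CO1 was still lower at 50 μM (log2 −2.89).

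**Figure D3:**
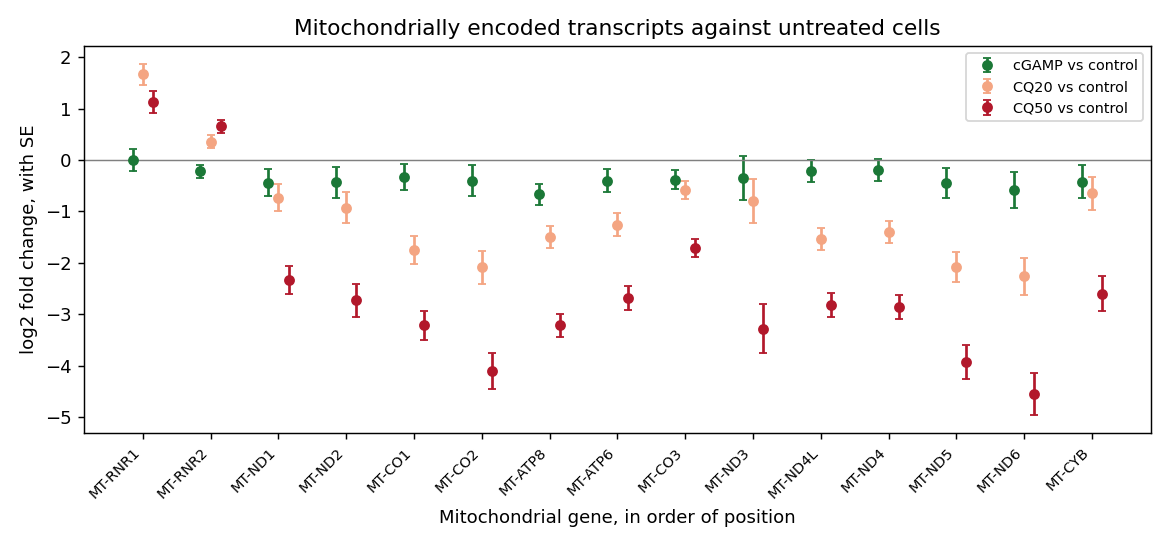
Log2 change ± SE against untreated cells for 15 mitochondrially encoded genes in position order with cGAMP, 20 μM and 50 μM chlorquinaldol. MT-RNR1 (1.67 and 1.13) and MT-RNR2 (0.36 and 0.66) lie above 0 with the drug while MT-ND6 falls to −4.56.

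Some of the largest single-gene changes fell outside the lists. SERPINB2, a plasminogen activator inhibitor gene (chromosome 18, 63871692 to 63903890), fell from 211 ± 16.2 to 5.72 ± 5.77 CPM at 20 μM (36.5-fold) and 1.37 ± 0.445 at 50 μM (155-fold); its neighbour SERPINB10, which overlaps it, fell at 20 μM too (log2 −3.52). The telomerase gene TERT fell 23.3-fold and 59.8-fold, and the calcium channel subunit gene CACNA2D3 by log2 −3.60 and −6.10. Leaving out CQ20 replicate 3 moved SERPINB2 to log2 −6.36, TERT to −5.59, CACNA2D3 to −4.26 and the antisense gene GJD3-AS1 from −4.39 to −8.06 at 20 μM (1 count left there), and without CQ50 replicate 1 CACNA2D3 was at −5.49 at 50 μM. NRCAM, a neural adhesion gene, had 2573 counts at 50 μM against 2 (ratio 1406, interval 389 to 11614) and AK8 342 against 2 (ratio 187, interval 51.3 to 1549).

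Monocyte genes rose in 7 and fell in 13 of 22 at 20 μM (8 and 14 adjusted over the list alone; 0.00937, and 0.275 with an estimated correlation), then 8 and 13, the same adjusted over the list alone (camera 0.0732; gained without control replicate 1, 0.0302, or control replicate 2, 0.0353; also gained with the replicate block, 0.0397; camera alternatives 0.0302 to 0.409). The calprotectin genes S100A8 (log2 −2.94 and −3.93) and S100A9 (−2.49 and −3.43) fell, while the integrin gene ITGAX rose (1.17 and 2.39). Macrophage differentiation genes rose in 6 and fell in 6 of 17, the same adjusted over the list alone, then 7 and 6 (8 and 6 adjusted over the list alone), with FABP4 (log2 2.95 and 5.75) and CD36 (2.61 and 3.94) higher. At 20 μM their median of −0.05 opposes the mean of 0.44 (camera 0.0754; 0.0173 without CQ20 replicate 1; camera alternatives to 0.558), and at 50 μM camera gave 0.0169 and the estimated correlation 0.409.

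Markers of other cell types were few and mostly low. B-cell markers rose in 3 of 3 at 20 μM and 1 at 50 μM, the same adjusted over the list alone (camera 0.136 and 0.627). Epithelial markers rose in 1 of 4 at 20 μM, the same adjusted over the list alone, and 2 rose and 1 fell at 50 μM (2 and 2 adjusted over the list alone), where the median of −0.22 opposes the mean of 0.49 (camera 0.657 and 0.59). Marker lists with fewer than 3 tested genes were not tested as lists. In the order untreated, cGAMP, 20 μM and 50 μM, T and NK cell genes had 590, 648, 690 and 834 counts, fibroblast genes 184, 144, 168 and 149, and erythroid and megakaryocyte genes 74, 59, 94 and 111.

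**Figure D4:**
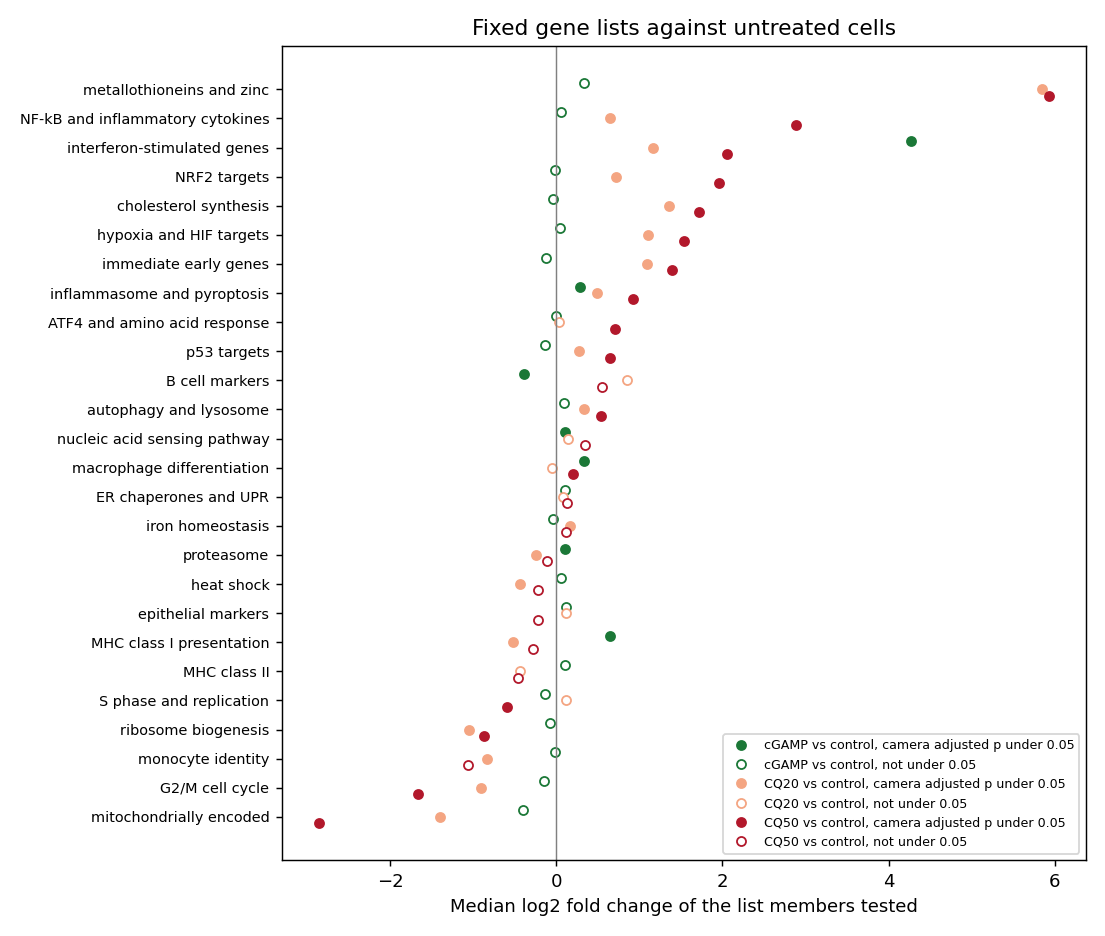
Median log2 change against untreated cells of 26 fixed gene lists for cGAMP, 20 μM and 50 μM chlorquinaldol, with low-count members at their bound. Filled points mark a camera adjusted p below 0.05; metallothioneins lie highest (5.85 and 5.93 with the drug) and mitochondrially encoded genes lowest (−2.86 at 50 μM).

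The doses were then compared directly, and 3168 genes were higher and 3159 lower at 50 μM than at 20 μM, 758 and 555 of them at least 2-fold. Several inflammatory genes rose steeply between the doses. EBI3, an interleukin subunit gene, went from 1.23 ± 0.232 to 27.6 ± 8.64 CPM (22.3-fold), CXCL2 rose 20.3-fold, IL1A 17.7-fold and CXCL8 11.8-fold. In the NF-kB and inflammatory list 36 of 38 rose and 1 fell (36 and 2 adjusted over the list alone), median 2.10, or 1.95 with a low-count member at its bound (adjusted p = 0.117 with an estimated correlation). NRF2 targets rose in 27 and fell in 2 of 30, the same adjusted over the list alone, with TXNRD1 3.99-fold higher (0.117 with an estimated correlation), and ATF4 targets in 28 and 1 of 37 (31 and 1 adjusted over the list alone; 0.117). Interferon-stimulated genes rose in 47 and fell in 1 of 56 (49 and 1 adjusted over the list alone), IFIH1 2.76-fold (0.264 with an estimated correlation). S-phase genes fell in 30 and rose in 1 of 33, the replication clamp gene PCNA 1.95-fold, and G2/M genes fell in all 29, TOP2A by log2 −1.27, the same adjusted over the list alone (0.117 and 0.182 with an estimated correlation). At the preset correlation camera called each of these lists between the doses (adjusted p from 1.38e-38 to 3.91e-12).

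Mitochondrially encoded mRNAs fell further at 50 μM, in 13 of 13, the same adjusted over the list alone (median −1.72, camera 0.27 with an estimated correlation). Camera at the preset correlation gave 1.6e-09. MT-ND6 was at −2.30 and MT-ATP8 at −1.72. The rRNAs were not called higher at 50 than at 20 μM: MT-RNR1 was lower (log2 −0.55, adjusted p = 0.0458) and MT-RNR2 was not called (0.30, 0.0824). Hypoxia genes rose in 27 of 36 (28 adjusted over the list alone), ANGPTL4 by log2 2.32. Cholesterol genes rose in 14 with 2 lower of 24 (16 and 2 adjusted over the list alone). Camera gave 1.06e-07 and 0.00119 at the preset correlation, and 0.412 for each with an estimated correlation. Metallothioneins stayed level between doses, with 1 higher, SLC30A2, and 1 lower, MT1G, of 12 (0 and 1 adjusted over the list alone; camera 0.223, but 0.00727 without CQ50 replicate 1; alternatives to 0.722). The kinase gene MAP2K6 fell 11.1-fold and the antisense gene CERS6-AS1 by log2 −4.31 ± 0.98 (adjusted p = 0.00208; lost in DESeq2, 0.0773; alternatives from 3.92e-50). The 20 counts of CERS6-AS1 at 50 μM were all in CQ50 replicate 2, so its fold has no estimate without that library, and it was at −3.70 without CQ50 replicate 3, MT-ND3 went from −2.48 to −3.28 without CQ50 replicate 1, and TFPI2 from 4.25 to 4.92 without CQ20 replicate 2.

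Chlorquinaldol at 50 μM was also set against cGAMP, with 5318 genes higher and 5768 lower. IFIT2 was 23.5-fold lower with the drug (37.3 ± 8.53 against 876 ± 58.1 CPM), the ubiquitin-like ligase gene HERC5 21.6-fold lower and IFNB1 106-fold lower. Interferon-stimulated genes were lower in 55 and higher in 1 of 56, the same adjusted over the list alone (median −2.36; adjusted p = 0.0948 with an estimated correlation), and at 20 μM all 56 were lower, the same adjusted over the list alone (median −3.22; 0.0269 with an estimated correlation). MHC class I genes were lower in 16 of 18 and higher in 1 at 50 μM, PSMB9 7.84-fold (0.0948 with an estimated correlation). CXCL8 was 82-fold higher with 50 μM while CCL8 was lower (log2 −5.12), and the NF-kB and inflammatory list had 34 higher and 4 lower of 38 (0.232 with an estimated correlation). At the preset correlation camera gave 6.52e-43, 2.3e-08 and 1.03e-15 at 50 μM for the interferon-stimulated, MHC class I and inflammatory lists. NRCAM was 424-fold, SUSD5 log2 7.95 and FLT1 7.44 higher, SERPINB2 −7.24 and NEXN −6.30 lower. Leaving out CQ50 replicate 1 moved SUSD5 to log2 7.26.

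Shared changes were asked across all 16628 genes. The doses moved together (r = 0.867 between log2 changes), with 3748 genes higher in both against 1449 expected from the separate counts, 4072 lower in both against 1615, and 134 opposite against 3060. cGAMP and 50 μM chlorquinaldol shared 1036 higher genes against 618 expected and 1041 lower against 678, with 851 opposite against 1296 (r = 0.234). For cGAMP and 20 μM the counts were 917 against 520, 910 against 547 and 697 against 1067 (r = 0.211). Both changes in a pair use the same 3 untreated libraries. Simulated groups without any real change but with shared controls reached a mean r of 0.489 to 0.493. Part of each excess may therefore come from the shared controls. Such groups shared at most 1 call (mean 0.1 over 10 refits), but without real change few genes are called at all. That count cannot show how far shared controls raise the overlap when many genes change. Covariance, which such noise raises little, was compared instead: simulated covariance was 0.0244 for the doses, against 0.772 observed, 0.0244 for cGAMP with 20 μM, against 0.0996, and 0.0245 for cGAMP with 50 μM, against 0.157.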

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

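All alternatives used here were chosen before the results were seen, and no direction of a named gene or count turned. Of the gene counts, at least 2-fold changes numbered 617 higher and 104 lower for cGAMP, 1459 and 1028 for 20 μM, 2393 and 2134 for 50 μM, 758 and 555 for 50 against 20 μM, and 2348 and 2183 for 50 μM against cGAMP. FPKM with limma gave fewer higher genes for cGAMP (1263 and 1247 with pseudocounts 1 and 0.1, 1085 without a filter) and for 50 against 20 μM (1839, 1750 and 1645). For cGAMP lower genes, the FPKM test without a filter gave 953 and an adjusted p below 0.01 gave 871; for 50 against 20 μM lower genes, that threshold gave 2089. Leaving out libraries moved the cGAMP lower count between 858 (without cGAMP replicate 2) and 1521 (without control replicate 3), with 1141 without cGAMP replicate 1, 1161 without control replicate 2 and 1173 without control replicate 1. The interferon-stimulated list lost its call with the estimated correlation at 20 μM (0.212) and 50 μM (0.178). Beyond these, the estimated correlation ended 78 of the 95 further list calls lost over all settings. List calls gained over all settings numbered 46, of which 31 came with fry, which does not compare a list with other genes. FOSB with cGAMP was lost in limma on FPKM (0.113; alternatives 1.24e-14 to 0.257), EGR3 (0.16, alternatives from 5.17e-43) and EGR1 (0.0593, alternatives from 4.79e-42) in limma without a filter, and CD79B in DESeq2 (0.15; alternatives 0.0288 to 0.453). In edgeR without a filter (35014 genes) the spread was pooled fully, with no finite prior degrees of freedom, so its p-values are too small and the lower ends of the ranges given for single genes come mostly from it. Chi-square per degree of freedom between replicate pairs, a measure of their spread, was 3.956 to 8.608 for untreated and cGAMP libraries. Chlorquinaldol libraries had 10.937 to 23.473. With only the groups compared, calls numbered 2820 higher and 2223 lower for cGAMP. They were 4505 and 4494 for 20 μM, 5313 and 5535 for 50 μM, and 2650 and 2484 for 50 against 20 μM. A replicate block gave 1842 higher and 1777 lower genes for cGAMP, 4391 and 4573 for 20 μM and 5281 and 5697 for 50 μM; it ended the call of CD79B (0.0588), and camera with the block gained monocyte identity at 50 μM (0.0397). The replicate numbers do not pair the libraries: correlations of same-number residuals ran from −0.113 to 0.067, and 2 of 12 libraries correlated best with their own number.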

Other observations

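The gene families, single genes and 6 of the tests in this part were chosen after the results were seen; the comparison with other splits was planned before. Zinc transporter transcripts moved with chlorquinaldol, in families picked after members in the fixed zinc list, among them SLC30A1 and SLC39A10, were seen to change. Of 8 SLC30 zinc exporter genes tested, 5 rose and 0 fell in edgeR at both doses (median log2 1.31 and 1.56), and of 11 SLC39 importer genes 8 fell at both doses while 2 and 3 rose (medians −0.46 and −0.37). SLC39A10 fell by log2 −2.33 and −2.50 and SLC39A14 by −1.58 and −1.21, while SLC39A8 rose by 0.27 and 0.29. Camera gave adjusted p = 8.98e-05 and 0.000854 for exporters (0.0175 and 0.0542 with an estimated correlation) and 0.000364 and 0.0128 for importers (0.0175 and 0.115). These p-values reuse the genes that prompted the families, which were not tested without them, so they are no independent test. CA2, whose product is a zinc enzyme, fell from 3346 ± 253 to 909 ± 347 and 369 ± 13.6 CPM (mean ± SD, n = 3).

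Nuclear genes of mitochondria fell against untreated cells, as did the mitochondrially encoded mRNAs. Complex I genes fell in 22 and 28 of 39 (4 and 3 rose) at 20 and 50 μM, and ATP synthase genes in 13 and 17 of 19. Between the doses the encoded mRNAs all fell further. The nuclear families changed less there, with medians of −0.08 for import genes and −0.17 to −0.23 for the others. Of 78 mitochondrial ribosomal protein genes 51 fell and 4 rose at 20 μM, and 59 fell and 6 rose at 50 μM (medians −0.43 and −0.53; adjusted p = 3.5e-06 and 9.33e-06 by camera, 0.406 and 0.426 with an estimated correlation). Of 25 import genes 21 and 23 fell, among them TIMM50 (log2 −0.94 and −1.02) and TOMM40 (−0.89 and −0.96; 0.174 and 0.283 with an estimated correlation), and of 17 mitochondrial aminoacyl-tRNA synthetase genes 11 and 15 fell (0.139 and 0.123). The mitochondrial RNA polymerase gene POLRMT fell by −0.90 and −0.82 and TFAM by −0.48 and −0.88, while TEFM rose by 0.39 at 20 μM (adjusted p = 0.0298) and was not called at 50 μM (0.31, 0.0709). Cytosolic ribosomal protein genes stayed level: 10 of 80 fell at either dose while 0 and 4 rose (medians −0.08 and −0.02; camera 0.281 and 0.774), and the 50 μM median is 0.03 under RLE scaling.

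The pattern of lower mitochondrial mRNAs beside higher mitochondrial rRNAs at 50 μM was weighed against scaling, nuclear copies and poly(A) capture. The log2 ratio of mRNA to rRNA counts within libraries was 1.98 ± 0.19 in untreated cells and −1.64 ± 0.73 at 50 μM. That difference of −3.61 restates the pattern rather than testing it anew, but library scaling cannot change a ratio within a library. Nuclear pseudogenes of mitochondrial genes (404 features) changed by −951 CPM while the mRNAs changed by −38821 CPM, which argues against reads assigned to nuclear copies. MT-ND6, whose mRNA has no poly(A) tail, changed by −4.56, but with strand unknown its reads may come from the opposite strand, so lower oligo(dT) capture stays open. Faster decay of the mRNAs could give this pattern and was not tested, nor was slower transcription.

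Interferon-stimulated genes rose at 50 μM with few interferon transcripts. If cGAMP RNA had been carried into these libraries, every gene strongly raised by cGAMP should reach about the 14% share of the median gene; NEXN reached 1.26%, and 8 of 26 such genes were below 0.5 of that share, which argues against carry-over. Library scaling moves all genes of a library alike, so it cannot change how the list moved relative to other genes. The list median was 2.06 while all 29 G2/M genes fell, which argues against library scaling as the source of that relative rise. The median of all 16628 genes (−0.034) is held near 0 by each scaling. It and the list median under other scalings (2.03 at the lowest) therefore decide nothing. A change in total RNA per cell, which would shift all genes alike, stays open. Interferon transcripts at 8 h had a ratio of 2.55 (interval 0.58 to 15.3; 7 against 3 counts), so an earlier or small interferon response may still explain the rise. An effect of the drug on signalling without interferon could do so too and was not tested.

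Other splits of the 6 libraries in each comparison were refitted in edgeR, and 10 splits are too few for a share under 0.05. The real split called 3875 genes for cGAMP, 9155 for 20 μM, 11123 for 50 μM, 6327 for 50 against 20 μM and 11086 for 50 μM against cGAMP, and in each comparison it was the 1 split of 10 with as many. The highest other split called 0, 0, 0, 1 and 0 genes. Every other split mixes libraries of both groups on each side, so a real difference enters the spread and few calls follow. The size of the gap in calls therefore adds nothing to the share of 1 in 10.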
